A study of Mus musculus with 4 samples.

How the data were processed

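RNA from regulatory T cells, the CD4+ T cells that restrain immune responses, was sequenced in 4 libraries of primary mouse cells of strain C57BL/6NJ. The labels put the 4 libraries in 1 group and number them as biological replicates 1 to 4. They give all 4 the same donor identifier, do not record sex, link a protocol for differentiating CD4+ T cells, and name the assay total RNA-seq while linking a library protocol named for polyA+ RNA-seq. The output names in the file headers carry the words activated and 24h. With 1 group there is no treated or control arm, so each comparison is between gene lists within a library or is a description of the spread between libraries. P-values measure only the spread between these 4 libraries, and nothing in the labels says whether they came from separate animals or cultures.

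Fragments per gene were counted by the authors with featureCounts version 1.4.6-p4, per the file headers, and the deposited values are raw counts, not normalized. Per the file headers, read pairs with both ends mapped were counted over exons grouped by gene, with strand setting 2 and GENCODE mouse release 13, on the mm10 assembly named in the labels. The command lines in the headers do not ask for reads that map to several places or that overlap 2 genes, so such reads did not count, which lowers genes with near-identical copies such as histones, H2-Q genes and T cell receptor variable genes. The aligner is not given in the sources used here beyond a tag in the name of the alignment file. The deposited tables also hold each gene's length in bp over the union of its exons, per the file headers.

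The planned design assumed tables with expected counts, TPM, FPKM and posterior means. The files hold counts, so counts were used as they stand, without rounding, and TPM (transcript abundance scaled for gene length and library total) and FPKM were computed from the counts and the exon union lengths. TPM of features far shorter than a fragment is inflated by this division. Names and gene types came from GENCODE mouse release 21 by gene ID without the version: 50376 of 50600 IDs matched and 224 did not. Coordinates are those in the deposited tables, mm10, counted from 1. The total was 38590127 fragments in replicate 1, 44357436 in replicate 2, 48312918 in replicate 3 and 93035969 in replicate 4. A count of 0 allows up to 3 fragments, which is 0.0777 to 0.0322 CPM (fragments scaled to a common library total) from the shallowest to the deepest library. Intervals are 95% exact binomial intervals. Intervals and floors cover counting error only. No pair of libraries was a duplicate: the chi-square statistic over its degrees of freedom was between 13.0 and 151 for the 6 pairs.

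The 36 gene lists, the tests, the alternatives, the rule for naming genes and the prediction about histone RNA were fixed before the data were examined. The lists cover T cells, 11 other cell types or T cell subsets (CD8, gamma delta, B, plasma, NK and innate lymphoid, macrophage and monocyte, dendritic, neutrophil, mast and basophil, erythroid and platelet, stromal and epithelial), regulatory T cell core and effector genes, Th1, Th2, Th17 and follicular helper (Tfh) genes, naive and memory, activation, thymus-associated regulatory and TGF-beta response genes, S phase, G2M phase, glycolysis, the TCA cycle, fatty acid oxidation, cholesterol synthesis, interferon response, immediate early and stress, apoptosis and p53, replication-dependent histones, pol III and structural RNAs, nuclear lncRNAs, Y-linked genes and Xist. Genes named are a fixed panel of 23, the 3 members of each list with the highest mean TPM and its lowest member where that was under 1, the 15 protein-coding genes with the highest mean TPM, and the 15 most variable genes by p. Some genes that this rule names are not reported here. A few further genes are named and said to have been chosen after their values were seen.

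List values are means of log2(TPM + 1) over the measured members in each library. Differences between lists were taken within each library and tested with an exact two-sided sign-flip permutation test, in which at least 2 of the 16 sign patterns reach any observed value, so no p under 0.05 is possible and they are reported as values with their spread. The median of each list was ranked among 10000 random lists of the same size, drawn from protein-coding genes with TPM of at least 1 in at least 1 library. The fixed lists kept members under that level, so a list with many low members ranks near 0 by construction. Genes that vary between libraries beyond genes of like abundance were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, an intercept-only quasi-likelihood fit with robust prior, the upper tail of the F distribution for the gene's dispersion over the prior, and Benjamini-Hochberg adjustment at 0.05. The filter left 12396 genes and removed the Y-linked list. On simulated counts for 12396 genes with 1 library changed, this test recovered 39 of 50 genes changed 2-fold, 45 of 50 changed 4-fold, 50 of 50 changed 8-fold and 50 of 50 changed 16-fold, with 1 false call among 185. The simulation gave each gene the dispersion of the fitted trend, without variation between genes of like abundance. Recovery and false calls may therefore be better there than in the real counts. Alternatives were a pseudocount of 0.1, FPKM, list medians, expressed members alone, other detection limits, other scalings, no filter, a non-robust prior, DESeq2 1.42.0 dispersion outliers, protein-coding genes alone, and each replicate left out. TPM without an rRNA-related locus and short features, variable genes without chromosomes X and Y, and the T cell contrast without Ighm, Cd74 and Cst3 were chosen after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The deposited text notes that list files were not used.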

Results

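Gene expression was measured by RNA-seq in 4 biological replicates of mouse regulatory T cells, with 38590127 to 93035969 fragments assigned to genes per library. Protein-coding genes with TPM of at least 1 numbered 10342 to 10401 per library, and 10095 reached that level in all 4. Across these 10095 genes, which are not independent replicates, Pearson's r of log2 TPM between pairs of libraries was 0.992 to 0.996. The median coefficient of variation of TPM was 7.95%. The most abundant protein-coding genes were those of translation, the cytoskeleton and protein folding. Eef1a1, a translation elongation factor, had 10619 ± 817 TPM (SD, n = 4), Rplp1 9146 ± 375, Actb 8253 ± 182, the chaperone Hsp90ab1 7650.4 ± 456 and Rpl8 7301 ± 477. Eef2, Rplp0, Rps2, Rpl4, mt-Co1, Rps15, Tubb5, mt-Nd1 and Eif5a were among those that followed, between 6547 and 3212 TPM. Ribosomal protein genes together held 11.7 ± 0.574% of TPM and mitochondrial genes 1.56 ± 0.293%.

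The first comparison addressed which cells the libraries hold. None of the 11 other lists marks CD4+ T cells outside the regulatory lineage, so the comparison cannot judge their share. Genes of T cell identity were abundant in every library, and markers of other cell types were near or below detection with few exceptions. All 20 T cell genes had a mean TPM of at least 10, and 15 reached 100. Trac, the constant region of the T cell receptor alpha chain (ENSMUSG00000076928.5, chromosome 14, 54220521 to 54224206, plus strand), had 1436 ± 156 TPM, the kinase Lck 823 ± 64.5, Cd5 724 ± 66.3, the coreceptor Cd4 540 ± 31.7 and Cd3e 186 ± 11.2. The CD8 coreceptor genes were low, with Cd8a at 1.11 ± 0.451 TPM and Cd8b1 at 21.8 ± 4.19.

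Of 95 genes that mark other cell types or T cell subsets, 18 had a mean TPM of at least 1 and 4 reached 10. These were Ighm, the immunoglobulin heavy chain mu constant gene, at 328 ± 27.6 TPM, the invariant chain gene Cd74 at 132 ± 10.99, the protease inhibitor Cst3 at 92.0 ± 5.09, and Cd8b1. Other B cell genes were far lower, with Igkc, the kappa light chain constant gene, at 2.69 ± 1.54 TPM and Cd79b at 1.98 ± 1.19. The neutrophil genes S100a8, S100a9 and Csf3r, the basophil gene Mcpt8 and the plasma cell genes Jchain and Tnfrsf17 had 0 fragments in all 4 libraries, which allows 0.0322 to 0.0777 CPM. Klra4, Ms4a7, Cd209a, Ms4a2, Ppbp and Dcn also had 0 fragments. Cd68 (5.44 ± 1.23 TPM), Batf3 (5.90 ± 0.949), the receptor kinase Kit (7.48 ± 1.47), Pecam1 (4.93 ± 0.366), Sdc1 (4.16 ± 0.755), Trdc (2.84 ± 0.185), Adgre1 (1.399 ± 0.321) and Epcam (1.33 ± 0.324) lay between 1 and 10 TPM. The remaining leading markers, Sox13, Tcrg-C1, Mzb1, Eomes, Klrd1, Tyrobp, Cd14, Cxcr2, Prss34, Itga2b, Klf1 and Pdgfrb, had means under 1 TPM, and Zbtb16 and Ebf1 were the lowest members of the gamma delta and B cell lists with fragments in 2 libraries each.

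On the log2(TPM + 1) scale the T cell list exceeded the 95 other genes by 7.47 ± 0.09 (SD, n = 4), in 4 of 4 libraries. Most of the 95 genes lay near 0, so the size of this difference depends on the scale: it was 9.90 with a pseudocount of 0.1, 6.02 with FPKM and 5.50 with expressed members alone. In the exact two-sided sign-flip permutation test 2 of the 16 sign patterns gave a mean as far from 0, the fewest that 4 libraries allow and too many to pass 0.05, and the same holds for every list difference below. The list mean was 8.10 ± 0.07 for T cells against 2.77 ± 0.09 for CD8, 1.69 ± 0.04 for dendritic, 1.20 ± 0.11 for B, 0.52 ± 0.05 for gamma delta, 0.52 ± 0.04 for mast and basophil, 0.51 ± 0.10 for plasma, 0.40 ± 0.05 for stromal and epithelial, 0.35 ± 0.04 for macrophage and monocyte, 0.14 ± 0.04 for NK and innate lymphoid, 0.11 ± 0.01 for erythroid and platelet, and 0.00 for neutrophil genes. The median of the T cell list lay at percentile 100 of the random lists of expressed genes.

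The second comparison addressed which helper program the cells carried beside the regulatory one. The core regulatory list was higher than each helper list in every library. Foxp3, the transcription factor that defines the lineage (ENSMUSG00000039521.12, chromosome X, 7579676 to 7595243, plus strand), had 109 ± 14.5 TPM. The TNF receptor family member Tnfrsf4 had 1344 ± 59.8 TPM, the interleukin-2 receptor genes Il2rb 767 ± 24.2 and Il2ra 702 ± 44.1 (chromosome 2, 11642807 to 11693193), and the inhibitory receptor Ctla4 245 ± 26.5 (chromosome 1, 60887000 to 60915832). Tnfrsf4 and Il2ra are also members of the activation list. Of 25 core genes, 21 had a mean TPM of at least 1 and 19 of at least 10. Nrp1 had 33.5 ± 4.54 TPM, Ikzf2, which encodes Helios, 4.32 ± 0.788, the integrin gene Itgae 1.63 ± 0.195, and Klrg1 had 0 fragments in all 4 libraries.

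Effector genes were uneven. Of 15, 8 had a mean TPM of at least 1: the inhibitory receptor gene Pdcd1 had 467 ± 17.9 TPM, Lgals1, which encodes galectin-1, 394 ± 23.3 and Tgfb1 237 ± 14.2. The cytokine gene Il10 had 0.201 ± 0.0988 TPM and Ido1 0 fragments. The effector list mean was 3.27 ± 0.04.

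Helper lineage lists held a few abundant genes and many low ones. Of 12 Th1 genes, 9 had a mean TPM of at least 1. The chemokine genes Ccl4 and Ccl3 had 379 ± 81.8 and 92.4 ± 19.9 TPM and the transcription factor Runx3 57.4 ± 2.91, while Tbx21, the Th1 master regulator, had 2.20 ± 0.877 and Ifng 0.420 ± 0.1246. Of 12 Th2 genes, 5 reached 1 TPM: Ccr4 had 148 ± 3.31, Il9 59.5 ± 9.99 and the transcription factor Gata3 25.9 ± 1.44, while Il4 had fragments in replicate 1 alone and Ptgdr2 in none. Of 11 measured Th17 genes, 7 reached 1 TPM: Ccr6 had 163 ± 4.57 and Ahr 44.6 ± 4.14, while Il17a had 0.690 ± 0.551 and Il23r 0 fragments. The cytokine gene Il17f, chosen after its values were seen, had 13.6 ± 0.997 TPM. Of 10 Tfh genes, 6 reached 1 TPM: Cd40lg had 224 ± 17.6, Il6ra 78.2 ± 6.17, Sh2d1a 42.9 ± 2.55 and Bcl6, the Tfh transcription factor, 4.02 ± 0.499, and Sostdc1 had 0 fragments. Hlx was the lowest Th1 gene, with fragments in replicates 1 and 4 alone.

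The core regulatory list, with a mean of 5.56 ± 0.06, exceeded the Th1 list (3.14 ± 0.10) by 2.41 ± 0.14 on the log2(TPM + 1) scale, the Th2 list (2.30 ± 0.02) by 3.26 ± 0.04, the Th17 list (2.75 ± 0.07) by 2.80 ± 0.12 and the Tfh list (3.08 ± 0.08) by 2.47 ± 0.06, each in 4 of 4 libraries (SD, n = 4). Among random lists of expressed genes the median of the core list lay at percentile 97.8, that of the regulatory effector list at 0, and those of the Th1, Th2, Th17 and Tfh lists at 0.06, 0, 0.1 and 2.13. The fixed lists kept low members that the random lists left out, which pulls their percentiles down. The Th2 difference fell to 1.32 and the Tfh difference to 1.46 when only members with TPM of at least 1 in a library were kept. The lists hold different genes, and no other T cell population was sequenced here for reference. These and the later list differences therefore depend on which genes were listed, and agreement between libraries does not change that.

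**Figure D1:**
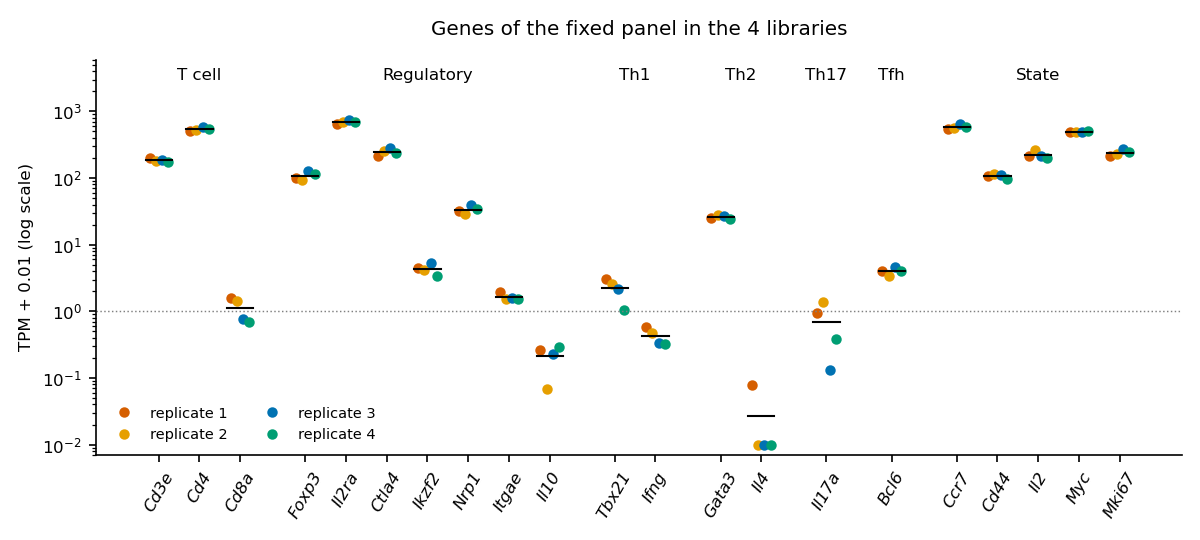
TPM + 0.01 (log scale) of 21 genes of the fixed panel, 1 point per library coloured by replicate, with a line at the mean of the 4 libraries and a dotted line at 1 TPM. Foxp3 (mean 109 TPM), Il2ra (702 TPM) and Ctla4 (245 TPM) lie above Tbx21 (2.20 TPM), Bcl6 (4.02 TPM) and Gata3 (25.9 TPM) in each library.

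The third comparison addressed the state of the cells. Genes of activation and of naive or memory T cells were both expressed, the activation list higher. All 20 activation genes and all 15 naive and memory genes had a mean TPM of at least 1. The highest activation gene was Tnfrsf4, which with Il2ra is also in the core regulatory list. The transcription factor Irf4 had 731 ± 42.4 TPM, Myc, a driver of growth, 497 ± 13.4, the T cell growth factor Il2 223 ± 26.4 and the adhesion receptor Cd44 108 ± 7.70. Of the naive and memory genes, the transcription factor Tcf7 had 789 ± 41.1 TPM, the homing receptor Ccr7 583 ± 41.0 and Igfbp4 238 ± 31.2. The activation list mean was 7.40 ± 0.07 and the naive and memory mean 6.05 ± 0.07, a difference of 1.36 ± 0.03 (SD, n = 4), higher in 4 of 4 libraries.

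Genes of division were expressed throughout. All 20 S phase genes had at least 10 TPM (list mean 7.94 ± 0.07), led by the ribonucleotide reductase subunit Rrm2 (822 ± 56.8 TPM), Pcna (816 ± 83.5) and the replication helicase subunit Mcm3 (766 ± 30.0). All 20 G2M genes also reached 10 TPM (7.03 ± 0.12), with Top2a at 374 ± 37.7, Cdc20 at 307 ± 22.7, Ccna2 at 262 ± 30.4 and Mki67 at 238 ± 24.0. The G2M mean was 6.85 in replicate 1 against 7.08 to 7.10 in the other libraries.

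Metabolic lists were led by glycolysis (8.01 ± 0.07), with Ldha, lactate dehydrogenase A, at 2802 ± 162 TPM, Pkm at 1389 ± 95.8 and Gapdh at 1231 ± 103. The TCA cycle list (7.55 ± 0.07) was led by Mdh2 at 511 ± 37.9, Sdhd at 484 ± 34.6 and Sdha at 356 ± 23.0. Fatty acid oxidation genes had a mean of 5.52 ± 0.06, with Acadvl at 156 ± 9.01, Etfa at 142 ± 14.2 and Acadl at 112 ± 5.52, and lay 2.49 ± 0.05 below glycolysis in 4 of 4 libraries. Cholesterol synthesis genes had a mean of 5.64 ± 0.08, with Hmgcs1 at 182 ± 10.7 and Cyp51 at 160 ± 12.97. All members of these 4 lists reached 10 TPM.

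Interferon response genes were mostly low: 8 of 20 reached 1 TPM (list mean 1.43 ± 0.01), with Bst2 at 238 ± 14.3 and Ifit2 at 17.2 ± 1.28, and Rsad2 had fragments in replicate 1 alone. In the immediate early and stress list (5.48 ± 0.06) 18 of 20 genes reached 1 TPM, with the heat shock genes Hspa8 at 2185 ± 129 and Hsp90aa1 at 1058 ± 93.9 and the AP-1 gene Junb at 714 ± 18.3, and the heat-inducible gene Hspa1a at 0.761 in replicate 2 and 0.0836 to 0.220 in the others. All 14 apoptosis and p53 genes reached 1 TPM (6.11 ± 0.08), with the cell cycle inhibitor Cdkn1a at 424 ± 23.7, Bax at 418 ± 46.0 and Bcl2l1 at 408 ± 15.3.

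**Figure D2:**
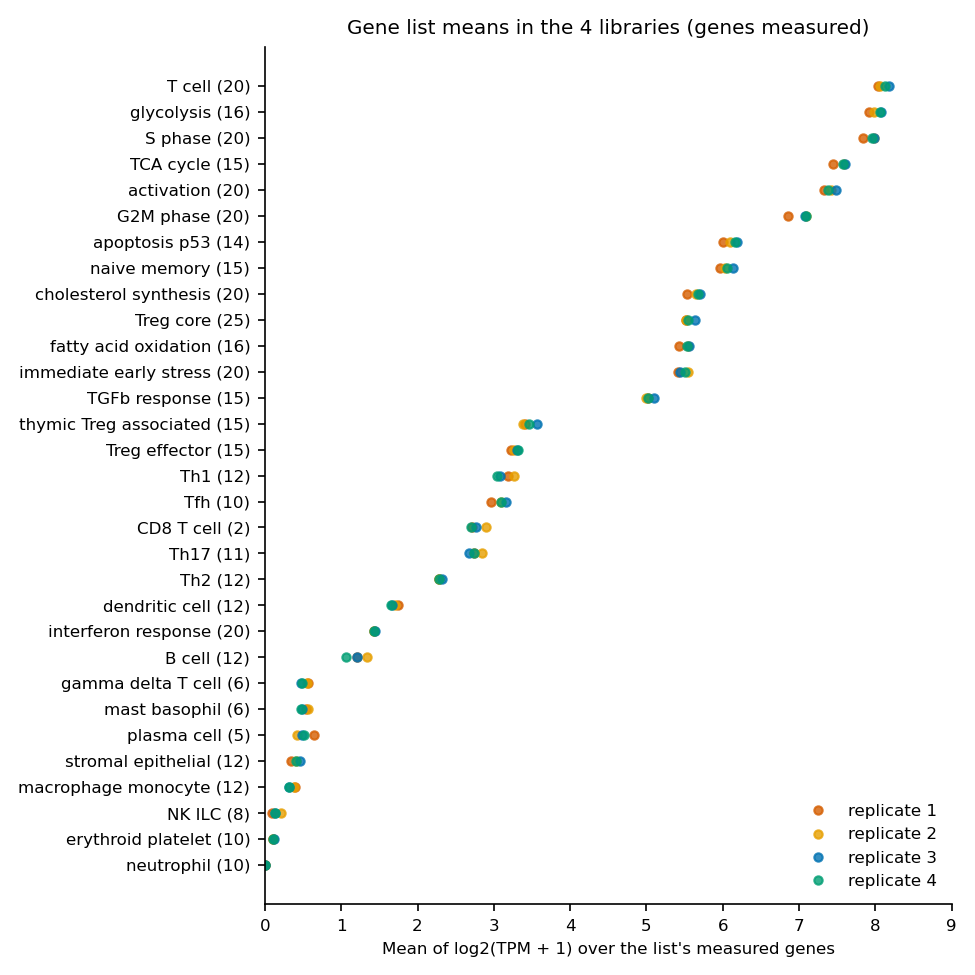
Mean of log2(TPM + 1) over the measured genes of each fixed list, 1 point per library coloured by replicate, with the number of genes measured in brackets. T cell (mean 8.10), glycolysis (8.01) and S phase (7.94) genes lie highest, and neutrophil genes lie at 0.00.

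The fourth comparison set genes associated with regulatory T cells of thymic origin against genes of the TGF-beta response, since the labels link a protocol for differentiating CD4+ T cells. TGF-beta response genes were the higher list. The chemokine receptor gene Ccr8 had 590.3 ± 34.2 TPM, Rgs16 262 ± 23.8 and Ski, a regulator of SMAD signalling, 132 ± 6.59, and 13 of 15 members reached 1 TPM, while Tgfbi had 0 fragments. Of 15 thymus-associated genes 11 reached 1 TPM, led by the actin-capping gene Capg at 454 ± 32.01, Cd83 at 122 ± 5.11 and Izumo1r at 92.0 ± 11.4. The thymus-associated median lay at percentile 2.385 of the random lists and the TGF-beta response median at 68.5. The thymus-associated mean was 3.45 ± 0.08 and the TGF-beta response mean 5.04 ± 0.05, a difference of -1.58 ± 0.04 (SD, n = 4), below 0 in 4 of 4 libraries. The lists were built from general knowledge and do not establish where the cells came from.

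The last comparison addressed what differed between the 4 libraries. By edgeR's quasi-likelihood dispersion, 58 of 12396 genes varied beyond genes of like abundance at a Benjamini-Hochberg adjusted p of 0.05, and 661 had an unadjusted p under 0.05. The common biological coefficient of variation was 10.7%. Of 299 tested genes in the fixed lists of cell types, T cell programs, cell state and metabolism, 1 passed, the chemokine gene Ccl4 (409 and 481 TPM in replicates 1 and 2, 307 and 318 in replicates 3 and 4, adjusted p = 0.00639). Adjusted over the list alone, 2 Th1 genes and 1 gene each of the Tfh, B cell, mast and basophil, and apoptosis and p53 lists passed. The regulatory, activation, naive and memory, cell cycle and metabolic lists had 0 by either adjustment. Without replicate 1 the count was 37, of which 31 were among the 58.

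Replicate 1 was the highest library for 37 of the 58 variable genes, of which 44 were protein-coding. Gm42418, a feature listed as related to 18S rRNA in the RefSeq table (ENSMUSG00000098178.1, chromosome 17, 39846958 to 39848788, plus strand), had 35490.5 TPM in replicate 1 and 3197, 1324 and 1606 in replicates 2 to 4 (edgeR adjusted p = 1.34e-24). Its neighbour Gm26917 had 1389 TPM against 221 to 523, Lars2, a mitochondrial leucyl-tRNA synthetase gene, 757 against 102 to 183, and the nuclear RNA Malat1 115 against 20.4 to 29.9. The short features Gm23935, Gm24187 and Gm24270, each 57 bp long, with Mir6236 and Gm15564, were between 6.31 and 7.37 times the mean of the other libraries. Rn7sk, the RNA that regulates transcription elongation, had 175 TPM against 3.01 to 7.05. All 12 variable histone genes were highest in replicate 1, Hist1h1e with 78.4 TPM against 11.4 to 18.5. Reads shared with other copies were not counted for these families, so their levels are uncertain.

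Shares of the library moved with them. The rRNA-related locus on chromosome 17 held 2.18% of fragments in replicate 1 (95% interval 2.177 to 2.186), 0.227% in replicate 2, 0.0918% in replicate 3 and 0.115% in replicate 4. Its mean share of TPM was 1.101 ± 1.73%, and 0.239% without replicate 1. Protein-coding genes held 88.2% of TPM in replicate 1 and 95.6%, 96.6% and 96.6% in the other libraries. By fragments the gap was smaller, at 96.8% in replicate 1 and 98.9%, 99.1% and 99.1% in the others. Features under 200 bp, whose TPM is inflated by the division by length, held 6.24% of TPM in replicate 1 but 0.120% of its fragments. The 19 measured histone genes held 0.0519% of TPM in replicate 1 and 0.0217 to 0.0262% in the others (list mean 3.49 ± 0.67), led by Hist1h3c, Hist1h4d and Hist1h3a at 43.4, 38.7 and 31.3 TPM. Of these genes 7 varied over all genes and 10 adjusted over the list alone. Among 11 pol III and structural RNAs (list mean 1.38 ± 0.38, with 1 of 2 tested members variable by either adjustment) Rpph1, the RNA of ribonuclease P, had 151 TPM in replicate 1 against 128 to 181 and did not pass the test (adjusted p = 0.976), Rmrp had 31.1 against 1.34 to 2.37 and was not tested, and Vaultrc5 had 0 fragments. Of 6 nuclear lncRNAs (1.85 ± 0.68), Xist and Malat1 varied over all genes and 3 adjusted over the list alone, Neat1 had 3.08 ± 0.548 TPM and Meg3 0 fragments.

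Genes of the sex chromosomes split the libraries in pairs. Xist, the RNA that coats the inactive X chromosome (ENSMUSG00000086503.3, chromosome X, 103460375 to 103483217, minus strand), had 100.4 and 88.7 TPM in replicates 1 and 2 and 0.716 and 0.603 in replicates 3 and 4 (edgeR adjusted p = 2.87e-24). The Y-linked genes lay the other way: Ddx3y had 0.159 and 0.101 TPM against 46.1 and 40.6, Eif2s3y 0.0596 and 0.145 against 42.4 and 49.3, and Kdm5d 0.0218 and 0.0199 against 10.9 and 8.92, without a test because the abundance filter removed them. All 6 variable X-linked genes were higher in replicates 1 and 2 than in replicates 3 and 4. The class I genes H2-Q6 (31.0 and 39.3 TPM against 6.43 and 11.6) and H2-Q7 (46.9 and 51.7 against 21.4 and 24.9), near-identical copies whose reads are hard to tell apart, and the cytokine receptor gene Il27ra (83.7 and 68.9 against 35.6 and 35.6) had the same order. The labels do not record sex and give the 4 libraries 1 donor identifier. Replicates 1 and 2 had the pattern of female cells and replicates 3 and 4 that of male cells. These values argue against a single animal as the source of all 4 libraries. Sex cannot be told apart here from any other difference between these pairs of libraries.

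**Figure D3:**
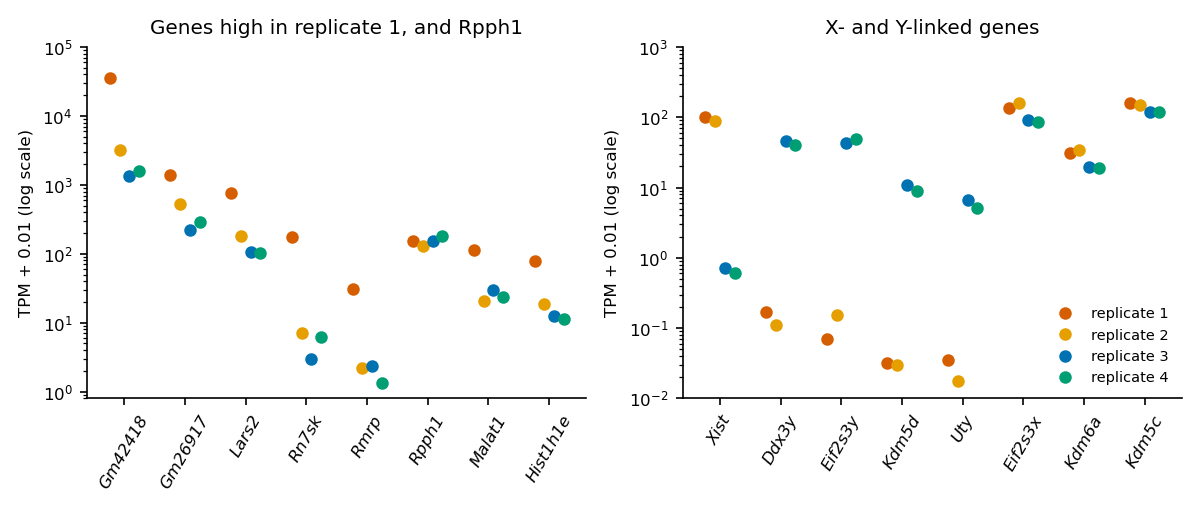
TPM + 0.01 (log scale) per library, coloured by replicate, of structural, nuclear and histone RNAs with Lars2 (left) and of X- and Y-linked genes (right). Replicate 1 lies highest for Gm42418 (35490.5 TPM) and Rn7sk (175 TPM) but not for Rpph1, and Xist and the Y-linked genes separate replicates 1 and 2 from replicates 3 and 4.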

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

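The tests of explanations in this part were chosen only after the values were seen. Of 224 results with 1 value per library and a value above 0 in at least 1, 39 had 1 library apart from the other 3 by Dixon's criterion. Of these 39, 32 were in replicate 1. Chance gives about 1 in 20 only for results not picked by their values, so it is no baseline here. Some of the genes were named for varying most or after their values were seen. A gene with fragments in 1 library alone always meets the criterion. The results also share libraries, so they are not independent.

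Replicate 1 was the high library for Gm42418 (35490.5 TPM), Gm23935 (42587 TPM), Gm24187 (9900 TPM), Gm24270 (1319 TPM), Gm15564 (132 TPM), Lars2 (757 TPM), Rn7sk (175 TPM), Rmrp (31.1 TPM), Malat1 (115 TPM) and Hist1h1e (78.4 TPM), for the histone list mean (4.49), and for the TPM shares of histones (0.0519%), the rRNA-related locus (3.69%) and features under 200 bp (6.24%). It was the low library for Pdcd1 (441 TPM), Lgals1 (360 TPM), Ccr4 (143 TPM), Top2a (318 TPM), Ldha (2560 TPM), Hspa8 (1994 TPM), Eef1a1 (9398 TPM), Rps2 (4375 TPM) and Rpl4 (4337 TPM), for the G2M list mean (6.85), for the protein-coding share of TPM (88.2%) and for the neutrophil list mean (0). Genes with few fragments also met the criterion. Replicate 1 was apart for Il4 (0.0674 TPM), Mzb1 (0.548 TPM), Prss34 (0.136 TPM), Rsad2 (0.0191 TPM), Eomes (0.219 TPM) and Cxcr2 (0 TPM), and replicate 2 for Cd14 (0.287 TPM).

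Technical explanations may account for the place of replicate 1, and with 1 group no biological one was set by the design. More cells in S phase would raise S phase genes with the histones, but after rescaling over protein-coding genes the 20 S phase genes had a median of 1.00 times the other libraries (0.842 to 1.16) against 3.23 times for the 19 histone genes, which argues against it. Carry-over of RNA without a polyA tail stays open: the high histone genes are the pattern itself and do not test it. Of the pol III and structural RNAs, Rpph1, at 0.979 times the other libraries by TPM, was not raised. Rn7sk was at 32.4 times and Rmrp at 15.8 times, but both are also part of the pattern. The protein-coding share of TPM was lower in replicate 1, which lowers the TPM of protein-coding genes as a set. Features under 200 bp held 6.24% of TPM there but 0.120% of fragments, so part of this comes from the division by short lengths. Over the detected protein-coding genes, the median in replicate 1 was 0.921515 times the other libraries by TPM and 1.00611 times after rescaling. Of the 9 named low genes with mean TPM of at least 1, 0 stayed apart after rescaling. Top2a moved from 0.810 to 0.884 times the others. Rescaling moves every gene of a library alike, and these genes were picked for being low. Whether dilution of TPM by the short features and the rRNA-related locus accounts for the whole drop in each of them therefore stays open. The rescaled G2M list mean in replicate 1 no longer stood apart by Dixon's criterion (ratio 0.736, under its critical value), yet differed from the others by -0.11 on the log2 scale, -6.25 SDs of those 3 libraries, so the tables do not settle it.

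The remaining results had another library apart. Batf3 had 7.32 TPM in replicate 3, Ahr 38.4 TPM in replicate 4 and Actb 7982 TPM in replicate 2. In replicate 3 the Th2 list mean was 2.33, the interferon response mean 1.44 and the erythroid and platelet mean 0.12.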

How the results depend on the processing

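The alternatives without the 3 B and dendritic cell genes and without chromosomes X and Y, and TPM without the rRNA-related locus and short features, were chosen only after the data were seen. All list differences kept their direction under each alternative that gave a value. Each moved by less than its SD when any 1 replicate was left out. For a mean of 4 values that is always so, and it does not test dependence on 1 replicate. The NK and innate lymphoid, neutrophil, and erythroid and platelet lists had no member with TPM of at least 1 in a library, so the expressed-member alternative gave no value for them. The T cell difference of 7.47 was 9.90 with a pseudocount of 0.1, 6.02 with FPKM, 5.50 with expressed members, 8.54 with medians and 7.68 without Ighm, Cd74 and Cst3. In the order pseudocount of 0.1, FPKM and median, the regulatory core difference was 2.77, 2.09 and 3.65 against Th1, 4.38, 2.62 and 5.34 against Th2, 3.399, 2.37 and 3.72 against Th17, and 3.31, 2.04 and 2.75 against Tfh. With expressed members it was 1.32 against Th2 and 1.46 against Tfh, where members near 0 no longer enter. Activation minus naive and memory was 1.30 with FPKM and 1.82 with medians. The thymic minus TGF-beta response difference was -1.80 with a pseudocount of 0.1, -1.34 with FPKM, -1.52 with expressed members and -1.74 with medians. Detected genes ranged from 8710.0 to 10547 over the other limits. The 58 variable genes became 110 without the low-count filter, which tests 21459 genes, and 36 with the non-robust prior, the cause of which was not tested. Leaving out 1 replicate gave 37 (without replicate 1) to 69 (without replicate 2). The remaining alternatives gave 40 to 69, with 49 without chromosomes X and Y and 58 of the 69 DESeq2 dispersion outliers shared. Of 158 gene levels rescaled over protein-coding genes, 38 moved by more than their SD. Over all 158 the ratio to the main value was at most 1.13, with a median of 1.06. The posterior mean TPM alternatives were not run, because the tables hold counts. Genes at 0 fragments are limited by depth, to 0.0777 CPM in replicate 1.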

Other observations

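The test on Ighm in this part was chosen only after its values were seen, and the genes of the cytokine, chemokine receptor and T cell receptor families were chosen after the data were seen. The test on histone RNA was fixed in advance. Cytokine genes were expressed unevenly: 25 of 65 named by family had a mean TPM of at least 1 and 8 at least 100. Lta, the lymphotoxin alpha gene, was the highest at 1970.1 ± 199 TPM (SD, n = 4), followed by Tnf at 367 ± 30.6, Tnfsf11, which encodes RANKL, at 338 ± 37.4, Ltb at 294 ± 34.1 and Lif at 266 ± 20.7. Il9 had 59.5 ± 9.99 TPM, Ebi3, a subunit of interleukin-35, 46.0 ± 7.98 and Il3 33.9 ± 8.31.

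Of 18 chemokine receptor genes, 8 reached 1 TPM. Ccr8, Ccr7, Ccr6 and Ccr4 were above 100 TPM, and Cxcr3 (17.6 ± 3.02), Cxcr5 (15.02 ± 1.21), Cxcr4 (11.7 ± 1.399) and Cxcr6 (9.01 ± 0.897) lay below them, while Ccr9, a gut homing receptor, stayed under 1 TPM in each library. The beta chain variable genes were used broadly: 21 of 22 had fragments in all 4 libraries, the effective number (the exponential of the Shannon entropy) was 15.6 ± 0.480, and Trbv31 held 11.1 ± 1.16% of their fragments, Trbv1 10.8 ± 2.33% and Trbv3 9.06 ± 0.686%. Of 108 alpha chain variable genes 61 had fragments in all 4 libraries, with an effective number of 41.7 ± 2.27. Near-identical copies lose reads in this counting, so the alpha chain shares are uncertain.

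The order of the libraries had replicates 1 and 2 on one side and 3 and 4 on the other in 39 of the 58 variable genes (67.2%), against 29.3% of all tested genes and 33.3% by chance. This count uses the order alone. It therefore includes genes such as Gm42418, where replicate 1 stood far above replicate 2 as well. Of the 58, 27 were 2-fold or more in replicate 1 over the mean of the others, so the count does not show a clean split into pairs. Of the 6 variable mitochondrial genes, 5 were higher in replicates 3 and 4, among them mt-Co1 at 5283 and 5760 TPM against 3925 and 4093.

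The labels name total RNA-seq and link a protocol named for polyA+ RNA-seq. Replication-dependent histone RNAs lack a polyA tail, and the prediction for polyA selection was a share under 0.1% of TPM in each library. The highest share was 0.0519%, in replicate 1, which met the prediction for polyA selection. The share covers only the 19 measured genes of the 37 in the fixed list. Reads shared between histone copies were not counted. Both limits lower the share and so favour the prediction. No library of known protocol was analysed here, so another protocol stays open.

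Ighm, at 328 TPM, was the highest marker of another cell type. B cells in the sample would bring their light chain RNA too, but Igkc was between 0.165% and 1.17% of Ighm by TPM in the 4 libraries, and Cd79a was at 1.03 ± 0.494 TPM, which argues against B cells as the source. Transcription of the heavy chain constant region in T cells may account for it as a hypothesis, but the counts are per gene and hold no exon or junction, so nothing here tests it. Ighm lies on chromosome 12, 113418558 to 113422730, minus strand.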
